A study of Homo sapiens with 4 samples.

How the data were processed

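RNA of the cytoplasmic fraction of SUM159 cells was measured in 4 libraries, 2 treated with H3B-8800 and 2 with DMSO for 12 hours. Per the labels' protocols the libraries were strand-specific, from polyA-selected RNA. HISAT2 version 2.0.4 and the builds hg38 and mm10 are named in the submitters' processing notes. The listed introns are human: 99.9% of them are introns of GENCODE release 29 on GRCh38, so coordinates are given on hg38, 1-based. How reads were counted, and whether by strand, is not given in the sources used here. Introns with an annotated exon on their own strand only had a median of 1.71 intronic reads per kb, those with one on the opposite strand only 0.709, and those with none 0.515. Overlapping and antisense genes are therefore uncertain.

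Each deposited file lists the same 142224 introns of 15902 genes, with 1 RefSeq transcript per gene, and gives 2 read counts and an RPKM value per intron, deposited without a header. The RPKM equals the first count scaled by intron length and a library total, from which totals of 58000000, 62000000, 64000000 and 64000000 reads were recovered. The second deposited count was never below the first. Its excess over the first was taken as reads that span the intron. This reading is inferred from the values: over 2350 genes the mean rank correlation with intron length within a gene was 0.42 for the first count and -0.04 for the excess. The excess may include reads whose gap passes over an intron without using its splice sites. In 8 of 12705 genes with at least 3 introns, some library had the same excess, of at least 10, at every intron; SLC38A3 is one. A read that spans several introns counts at each of them, so sums per gene are not numbers of molecules. Even numbers made up 70.9% to 72.3% of the non-zero intronic counts per library, so both mates of a pair were probably counted and reads are not independent. For 18 introns of at most 10 bp no second count was given, which left 142206.

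The design fixed before the data were examined expected transcript-level TPM values. The files held counts per intron, so counts were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), as that design provides for counts, and p values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. For the gene-level result, spliced reads were summed per gene, genes with a mean of at least 1 CPM (counts scaled to equal library size) were tested, and TMM scaling was used. In place of transcripts, intronic reads per intron were tested with the recovered library totals, for introns with a mean of at least 10. In place of the share of intron-retaining isoforms, intronic and spliced counts of an intron entered 1 model with a term per library, a term for the kind of read and its interaction with treatment, for introns with a mean of at least 10 reads of each kind. SEs were approximated from the F statistic. Exon skipping and genes without introns were not analysed here; genes were compared by intron number instead. Genes without a listed intron, among them those of the nuclear non-coding RNA and mitochondrial lists, were not analysed here.

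The 26 gene lists, of 653 entries, were fixed before the data were examined. Of these, 22 had at least 3 tested genes and were tested with camera (limma 3.58.1), with a preset correlation of 0.01 and with an estimated one. With an estimated correlation, camera has only the residual degrees of freedom of the 4 libraries, so a list can fail for lack of power. Gene symbols were matched by RefSeq accession to the GRCh38.p14 gene table for 98.4% of genes. The genes named are the 8 largest rises and 8 largest falls that passed, with groups that do not overlap and at least 10 CPM in the higher group; members of each list among the 3 with the smallest adjusted p; and SF3B1 and PHF5A whatever their values. MCL1, MALAT1 and NEAT1, also named in the rule, were not analysed here. The introns named are among the 5 with the smallest adjusted p in each direction. Other genes named (GINS1, ORC1, SMG6) were chosen after their values were seen.

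The tests were tested on simulated counts drawn from the means and library totals of the real libraries, with 200 changed genes or introns. At 1.5-, 2- and 4-fold, the gene test recovered 71.6%, 92.5% and 100% over 9468 genes. The test of intronic reads recovered 2.99%, 13.4% and 72.7% over 12013 introns, and the ratio test 1.49%, 5.97% and 66.7% over 9937 introns, so most small changes of single introns were missed. A first requirement of over 80% recovery at 4-fold was not met by the intron tests and was dropped; the median sizes estimated at 4-fold were 2.04 and 1.90 on the log2 scale, against a true 2. With every other intron raised, the ratio test recovered 9.66%, 34.6% and 90.2%. False calls were at most 0.95% of unchanged features. Of 200 random lists, camera gave 4 a p under 0.05. The simulated genes and introns were drawn independently, with 1 dispersion per kind of read and without doubled mates. These rates therefore need not hold for the real counts.

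The series describes the libraries as biological replicates, and p values measure only the spread between these samples. The chi-square of intronic counts per degree of freedom was 2.56 within H3B-8800 and 2.55 within DMSO, against 18.9 between the first libraries of the groups, and that of spliced counts 3.80, 3.52 and 78.5. With each fragment counted at both mates, sampling noise alone gives more than 1, and its expected size was not computed, so these values do not show whether replicates differ beyond it. Alternatives were other scalings, filters and tests (DESeq2 1.42.0, limma), introns without an annotated exon inside, a block by sample number and leaving out each library. Planned changes of a pseudocount for genes, FPKM values and removal of mitochondrial genes had no counterpart in counts and were not run.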

Results

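Cytoplasmic polyadenylated RNA was sequenced from SUM159 cells, an established human breast cancer line of the triple-negative type. The cells had received either H3B-8800, a small molecule inhibitor of the spliceosome, or DMSO, its solvent, for 12 hours. Each group had 2 libraries. For 142206 introns of 15902 genes, 1 transcript per gene, the files gave the reads inside the intron (intronic reads) and allowed the reads that spanned it (called spliced reads here) to be computed. The library totals were 58000000 and 62000000 reads with H3B-8800 and 64000000 in each DMSO library. Intronic reads numbered 1035695 and 1126434 with H3B-8800, against 629498 and 628580 with DMSO. Spliced reads, counted once per intron, numbered 11605061 and 12536423 with H3B-8800 and 14240258 and 14194422 with DMSO. The comparison asks what inhibition of splicing did to intron-containing and to spliced RNA in the cytoplasm.

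Intronic reads made up a larger share of the cytoplasmic RNA after H3B-8800. They were 8.22% ± 0.036 (SD, n = 2) of intronic plus spliced reads with H3B-8800 and 4.24% ± 0.0051 (SD, n = 2) with DMSO, a ratio of 1.94. In introns without an annotated exon inside, the share was 5.32% ± 0.059 with H3B-8800 and 2.06% ± 0.019 with DMSO (SD, n = 2 each), a ratio of 2.58. Both H3B-8800 libraries lay above both DMSO libraries, by far more than the spread between replicates. With 2 libraries against 2, a two-sided exact permutation test cannot give a p below 0.333.

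**Figure D1:**
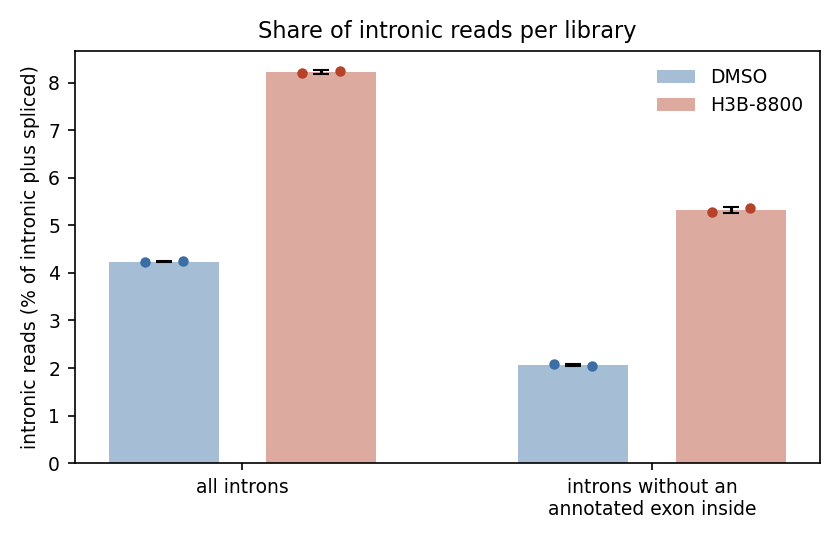
Intronic reads as a percentage of intronic plus spliced reads, over all introns and over introns without an annotated exon inside; bars are means of 2 libraries, points are libraries and error bars are SDs. The H3B-8800 libraries lie at 8.19% and 8.24% over all introns, and the DMSO libraries at 4.23% and 4.24%.

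Some introns had many intronic reads with H3B-8800 and few with DMSO. In HSP90AA1, which encodes a cytosolic chaperone, intron 9 (hg38 chromosome 14, 102081822 to 102082110) had 559 and 602 intronic reads with H3B-8800 and 4 and 4 with DMSO, and its intronic-to-spliced ratio rose by 7.58 on the log2 scale (SE 0.32; edgeR, Benjamini-Hochberg adjusted p = 8.1e-08). Intron 6 of MAPRE1, a microtubule plus-end protein (chromosome 20, 32846771 to 32848671), had 2119 and 2323 intronic reads against 67 and 48, a ratio change of 5.75 (SE 0.26). The ratio also rose in intron 1 of RPL9, a ribosomal protein gene (chromosome 4, 39458310 to 39458393; 6.71, SE 0.32). In intron 5 of GNB2L1, now RACK1, which encodes a ribosome-bound scaffold protein (chromosome 5, 181238240 to 181239066), the ratio rose by 5.33 (SE 0.25). The introns of RPL9 and GNB2L1 overlap annotated exons, unlike those of HSP90AA1 and MAPRE1, so their intronic counts are less certain. Ribosomal protein genes also have many processed pseudogenes, which may affect their reads.

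Across the 9937 introns with enough reads of both kinds, in 5342 genes, the ratio was higher with H3B-8800 in 5616 introns of 3525 genes and lower in 286 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The median change was 1.62 on the log2 scale, or 3.07-fold. Among the 739 tested introns that lie in an exon of an annotated retained_intron transcript, 501 were higher and 7 lower. Without H3B-8800 replicate 1 the lower ratios numbered 133, and without replicate 2 they numbered 137. Of the 286 introns with a lower ratio, 74.5% overlapped an annotated exon, against 46.1% of those with a higher one and 52% of all tested introns. The lowered introns were also longer, with a median of 12785 bp against 2254.5 bp for raised introns and 3029 bp overall. The 5 lowered introns with the smallest adjusted p all overlapped one. They were intron 1 of GAREM (now GAREM1), with a ratio change of -5.19 (SE 0.34), and intron 4 of PARPBP (-3.40, SE 0.33). The others were intron 3 of ARIH2 (-2.80, SE 0.31), intron 1 of SSR4 (-1.74, SE 0.22) and intron 2 of PHTF1 (-2.94, SE 0.37). A rise of spliced reads also lowers this ratio. In GAREM, spliced reads numbered 247 and 209 against 4 and 5 with DMSO, while intronic reads rose by 0.52 on the log2 scale. The DMSO libraries differed there, with 3858 and 7084 intronic reads. Intronic reads fell in PARPBP (-0.87), whose spliced reads rose, and in ARIH2 (-3.50), SSR4 (-1.15) and PHTF1 (-3.20).

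Intronic reads alone, scaled to the library totals, were higher in 5793 of 12013 tested introns and lower in 689, and 89.4% of the calls were rises. TMM scaling of the intronic reads themselves, which centres the changes on 0, left 2566 rises and 2322 falls, or 52.5% rises, and moved the median change from 1.13 to 0.09 on the log2 scale. Without either H3B-8800 library no intron passed (edgeR, smallest Benjamini-Hochberg adjusted p = 0.101 and 0.104), although 4367 and 4280 introns had an unadjusted p under 0.05 and DESeq2 called 1973 and 1868 rises and 178 and 220 falls. The spread then rested on the sparse DMSO pair. The prior degrees of freedom, the weight edgeR gives to the spread shared by all introns, went from 8.71 to 0.906 and 0.907. Without DMSO replicate 1 or 2 they went to 219 and 229, so the number of calls with a library left out is unstable. All 6482 introns called with 4 libraries kept their direction, but they were chosen on these same libraries, so this adds little support.

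The rise of intronic reads differed with intron length and place, in classes that were not matched on expression. In introns of up to 150 bp without an annotated exon inside, intronic reads per 100 spliced reads were 1.14 ± 0.026 with H3B-8800 and 0.320 ± 0.0039 with DMSO (SD, n = 2 each), a ratio of 3.58. In introns over 10000 bp they were 21.7 ± 0.068 and 15 ± 0.11, a ratio of 1.45. Last introns had 7.31 ± 0.0082 against 2.04 ± 0.023, a ratio of 3.59, and first introns 4.82 ± 0.13 against 2.56 ± 0.0012, a ratio of 1.89. Within introns over 1000 and up to 3000 bp the ratio was 3.91 in last, 3.11 in internal and 2.32 in first introns. Last introns had a higher ratio than first ones in 5 of the 6 length classes. Up to 150 bp the ratio was 5.53 in first, 4.23 in last and 3.14 in internal introns.

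**Figure D2:**
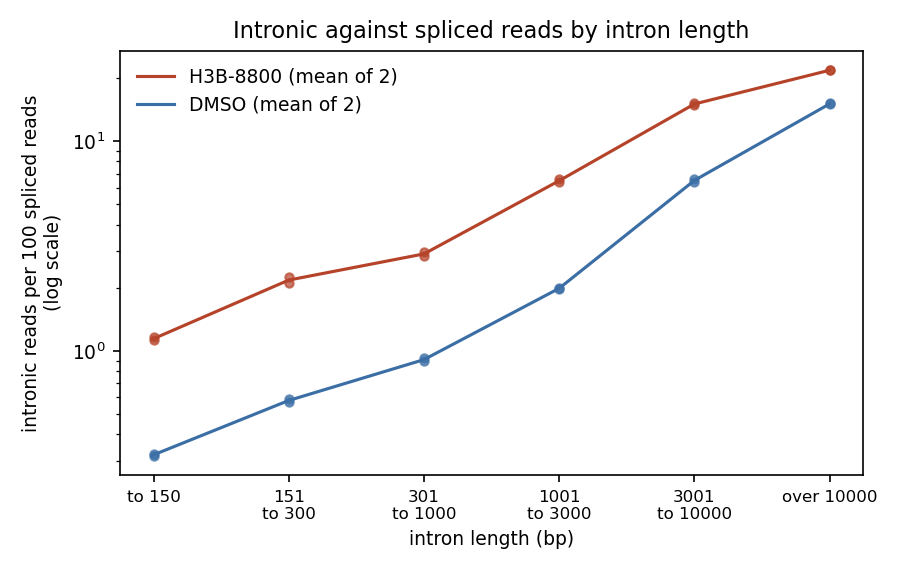
Intronic reads per 100 spliced reads (log axis) in 6 classes of intron length, for introns without an annotated exon inside; points are the libraries and lines join the means of the 2 libraries of each group. The gap between H3B-8800 and DMSO narrows from a ratio of 3.58 in the shortest class to 1.45 in the longest.

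Spliced reads changed in many genes, in both directions. Of 9468 genes, 3102 had more spliced reads with H3B-8800 and 3097 fewer (edgeR's quasi-likelihood test with TMM scaling, Benjamini-Hochberg adjusted p under 0.05); 608 rose and 1014 fell at least 2-fold. Of the calls, 50% were rises, against 36.2% (2230 rises and 3927 falls) when libraries were scaled to their totals, which moved the median of all genes to -0.16 on the log2 scale. Changes below are relative to the TMM scale.

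The 8 largest rises that passed included those of NUPR1, CHAC1, KITLG and SULT1E1. Spliced reads of NUPR1, a stress-induced transcriptional regulator, went from 4.33 ± 0.86 to 27.3 ± 2.0 CPM (counts scaled to equal library size; SD, n = 2 each), a log2 change of 2.69 (SE 0.17; edgeR, Benjamini-Hochberg adjusted p = 1.83e-08). This was measured at the 1 intron listed for NUPR1. CHAC1, a glutathione-degrading enzyme, rose by 2.5 (SE 0.26), KITLG, the ligand of the KIT receptor, by 2.32 (SE 0.13), and SULT1E1, an oestrogen sulfotransferase, by 2.44 (SE 0.10). HDX (3.38, SE 0.27), the zinc finger gene ZNF350 (2.99, SE 0.20) and the transporter gene SLC12A8 (2.77, SE 0.24) rose as well. The rise of GAREM (4.08, SE 0.23) came from its first intron, with 247 and 209 spliced reads against 4 and 5; without that intron its change was 0.16 (edgeR, Benjamini-Hochberg adjusted p = 0.812; range over alternatives 1.37e-30 to 0.812).

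The largest falls included COL13A1, a transmembrane collagen, from 28.8 ± 2.8 to 2.77 ± 1.4 CPM of spliced reads (SD, n = 2 each), a log2 change of -3.36 (SE 0.23; edgeR, Benjamini-Hochberg adjusted p = 3.97e-08). TMEM120B (-3.09, SE 0.14), CCDC61 (-3.03, SE 0.26), NECAB3 (-3.0, SE 0.24), NBEAL2 (-2.91, SE 0.18), SEC14L2 (-2.83, SE 0.15) and TRMT61B (-2.75, SE 0.33) fell as well. In TMEM120B, the gene's intronic-to-spliced ratio rose by 5.90 (SE 0.33), and in NBEAL2 by 3.34 (SE 0.37). It rose by 3.54 (SE 0.53) in TRMT61B, 3.12 (SE 0.57) in NECAB3 and 2.08 (SE 0.52) in CCDC61. A fall of spliced reads from any cause raises this ratio, so it does not by itself show more intronic reads in these genes. SLC38A3 also met the rule for a named fall, but its reads came from 1 library: DMSO replicate 2 had 675 spliced reads, the other DMSO library 1 and both H3B-8800 libraries 0. It did not pass with quantile normalization or limma without trend, nor without that library or without either H3B-8800 library (edgeR, Benjamini-Hochberg adjusted p = 0.342, 0.211 and 0.22; range over alternatives 8.2e-10 to 0.342).

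Genes with many introns fell more often. Of 1112 genes with 20 or more introns, 46.3% fell and 25.8% rose; of 2768 genes with 1 to 4 introns, 21.8% fell and 32.4% rose. The median log2 change was -0.21 in the first class and 0.11 in the second, a difference of -0.33. Taken per library, the difference between these classes was -0.15 and -0.18 with H3B-8800 and 0.15 and 0.16 with DMSO. These values nearly cancel over the libraries, so the sign within a group is not a result on its own. Only the contrast between the groups is. The spread of the group difference was 0.029.

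Genes of DNA replication fell together. Of 33 tested members, 28 fell and 2 rose, with the same counts adjusted over the list alone, and the median log2 change was -1.05. CDC45, part of the replicative helicase, went from 198 ± 2.4 to 37.5 ± 2.1 CPM of spliced reads (SD, n = 2 each), a log2 change of -2.37 (SE 0.07; edgeR, Benjamini-Hochberg adjusted p = 8.54e-11). The licensing factor CDC6 fell by 2.06 (SE 0.07) and the helicase subunit MCM7 by 1.91 (SE 0.06). The 2 members that rose were GINS1 (1.27, SE 0.11) and ORC1 (0.34, SE 0.10). The list passed camera with its preset correlation (Benjamini-Hochberg adjusted p = 6.32e-19, p = 2.87e-20) but not with an estimated one (p = 0.00876, adjusted p = 0.193 with an estimated correlation). The estimated correlation was -0.013, below the preset 0.01, so the weaker result does not show that correlated genes made the call.

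Most genes of the integrated stress response, which are the transcription factor ATF4 and its targets, rose. Of 18 tested, 12 rose and 2 fell, also when adjusted over the list alone, with a median log2 change of 0.71. The members with the smallest adjusted p were NUPR1, the amino acid transporter gene SLC7A5 (0.96, SE 0.06) and PSAT1, a serine synthesis enzyme (1.01, SE 0.07). Camera gave a Benjamini-Hochberg adjusted p of 8.32e-04 with the preset correlation (p = 1.13e-04) and an adjusted p = 0.585 with an estimated correlation.

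The genes of the splicing machinery moved in both directions. Of 20 genes of SF3b and the U2 complex, 13 rose and 3 fell, with the same counts adjusted over the list alone. SF3B1, the largest SF3b subunit, rose from 70.4 ± 2.6 to 112 ± 11 CPM of spliced reads (SD, n = 2 each), a log2 change of 0.71 (SE 0.08; edgeR, Benjamini-Hochberg adjusted p = 3.0e-06), measured over the 3 introns of the transcript listed. PHF5A, another SF3b subunit, had a change of -0.03 (SE 0.08; edgeR, Benjamini-Hochberg adjusted p = 0.746); scaled to library totals it was -0.21 and passed (adjusted p = 0.0427; range over alternatives 0.0427 to 0.963). U2SURP (-0.91, SE 0.06) and DDX46 (-0.59, SE 0.05) fell, and RBM17 rose (0.57, SE 0.04). Of 39 other core spliceosome genes, 23 rose and 10 fell, again also adjusted over the list alone. EFTUD2, a GTPase of the U5 particle, fell from 484 ± 1.7 to 190 ± 4.9 CPM of spliced reads, and SLU7 (1.18, SE 0.06) and SYF2 (1.16, SE 0.07) rose. Of 20 SR proteins and their kinases, 11 rose, among them SRSF5 (1.00, SE 0.05) and SRRM1 (0.79, SE 0.05), and 7 fell, among them SRSF7 (-0.84, SE 0.05), with unchanged counts adjusted over the list alone. Of 24 hnRNP genes, 8 rose and 11 fell, as they did adjusted over the list alone, and HNRNPU (-1.16, SE 0.04), HNRNPD (-1.04, SE 0.04) and HNRNPAB (-0.73, SE 0.04) were among the falls. None of these 4 lists passed camera: Benjamini-Hochberg adjusted p values were 0.178, 0.184, 0.178 and 0.282 with the preset correlation (p = 0.0529, 0.0751, 0.0613 and 0.128), and 0.717, 0.585, 0.585 and 0.774 with an estimated correlation.

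Most ribosomal protein genes rose by small amounts, and factors of nonsense-mediated decay, which destroys transcripts with early stop codons, and of the exon junction complex (together called decay factors here) moved in both directions. Of 18 decay factors, 10 rose and 5 fell, likewise adjusted over the list alone; RNPS1 (1.07, SE 0.06) and EIF4A3 (0.77, SE 0.05) were among the rises and SMG6 (-1.76, SE 0.24) among the falls. Of 71 ribosomal protein genes, 49 rose and 8 fell, or 50 and 10 adjusted over the list alone, with a median log2 change of 0.21. RPL10 (0.92, SE 0.06), measured at the 1 intron listed for it, and RPL5 (0.51, SE 0.03) rose, and RPLP0 fell (-0.61, SE 0.03). With the preset correlation camera gave Benjamini-Hochberg adjusted p values of 0.0422 for decay factors (p = 0.00767) and 8.32e-04 for ribosomal proteins (p = 7.81e-05), against an adjusted p = 0.585 with an estimated correlation for each. Scaled to library totals, the medians were 0.01 and 0.03 and neither list passed. Decay factors also did not pass without H3B-8800 replicate 1, H3B-8800 replicate 2 or DMSO replicate 1 (camera, Benjamini-Hochberg adjusted p = 0.117, 0.11 and 0.0724), nor without each gene's most-read intron or with its lowest count subtracted (adjusted p = 0.0502 and 0.0748).

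The antiviral and death receptor genes that could be tested did not differ from other genes by camera. Of 50 interferon-stimulated genes on the list, 30 were tested. Of these, 8 rose and 8 fell, or 8 and 7 adjusted over the list alone, with a median of 0.06 and a mean of -0.05. The median was -0.11 with library totals and -0.16 in introns without an annotated exon. Without each gene's most-read intron it was -0.08, and with its lowest count subtracted -0.36. SP100, a nuclear body protein, rose (1.09, SE 0.05), and IFI35 (-1.90, SE 0.15) and IFI44 (-0.67, SE 0.07) fell. Of 20 RNA-sensing genes, 8 rose and 6 fell, the same as adjusted over the list alone, with rises of the kinase gene TBK1 (1.14, SE 0.06) and the RNA editor gene ADAR (0.65, SE 0.08) and a fall of PRKRA (-0.95, SE 0.09), which did not pass with its gene's lowest count subtracted (-0.05). Of 24 interferon, cytokine and chemokine genes on the list, only 5 were tested, so most of that list was not measured. Of the 5, 1 fell, with the same count adjusted over the list alone: CXCL8 (-1.19, SE 0.15). CXCL2 (-0.66, SE 0.31) and IL6 (0.36, SE 0.26) did not pass, except CXCL2 scaled to library totals (-0.84) or by limma without trend. Of 20 NF-kB targets and regulators, 9 rose and 5 fell, or 10 and 5 adjusted over the list alone, with rises of TNFAIP2 (0.97, SE 0.08) and RELA (0.57, SE 0.06) and a fall of NFKB2 (-0.79, SE 0.08). Of 16 genes of extrinsic apoptosis, 8 rose and 2 fell, also adjusted over the list alone; the rises included TNFRSF10D, a decoy receptor (1.68, SE 0.17), and TNFRSF1A (0.56, SE 0.04). Camera's Benjamini-Hochberg adjusted p values for the 5 lists were 0.659, 0.525, 0.725, 0.525 and 0.178 with the preset correlation (p = 0.479, 0.307, 0.626, 0.31 and 0.0648), and 0.774, 0.774, 0.774, 0.767 and 0.585 with an estimated correlation. By fry, which tests whether a list's genes move on balance one way and compares them with no others, Benjamini-Hochberg adjusted p values were 0.0265, 0.0957, 0.0383, 0.0122 and 0.0122.

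**Figure D3:**
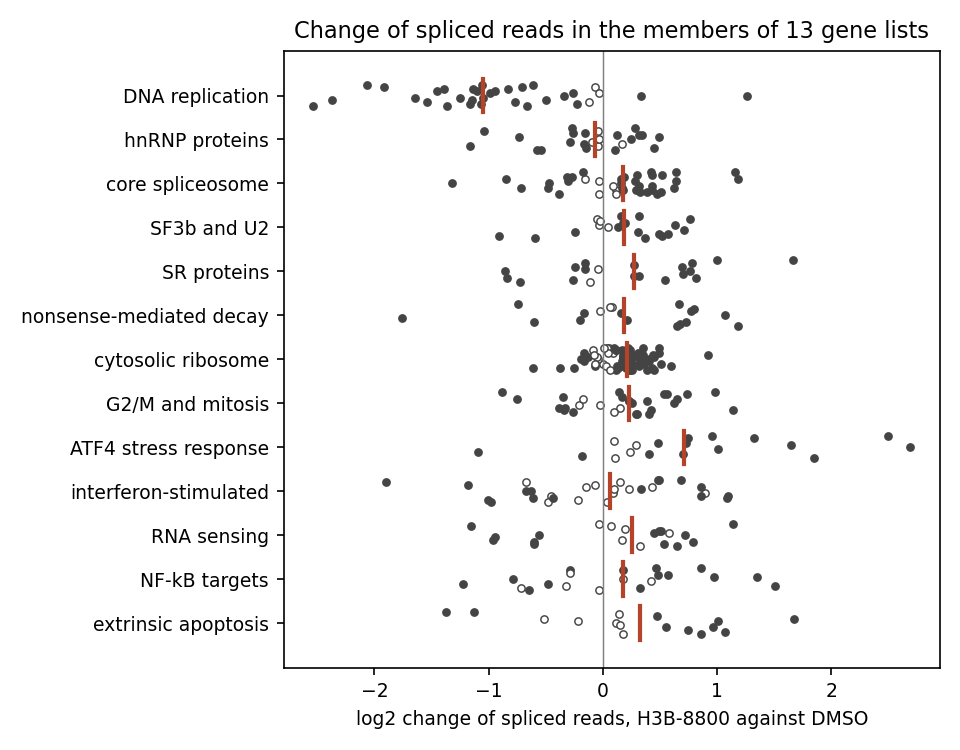
Log2 change of spliced reads, H3B-8800 against DMSO, for the tested members of 13 gene lists; each point is a gene, filled where the Benjamini-Hochberg adjusted p from edgeR was under 0.05, and the red line is the list's median. The median of the DNA replication genes lies at -1.05 and that of the integrated stress response genes at 0.71.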

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

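Alternatives added after seeing the data were the library totals for genes and lists, TMM for intronic reads, DESeq2, limma with trend, limma on RPKM and on log ratios, the filter of 40 intronic reads alone, introns without an annotated exon inside, the omission of each gene's most-read intron or of the 100 introns with most intronic reads, and subtraction of each gene's lowest count. Subtracting each gene's lowest count left 2024 rises of spliced reads, tested fewer genes (8386), moved the difference between many-intron and few-intron genes to -0.36 and turned KRT8 to 0.0039, where it did not pass. Of the 6199 genes called, 5327 remained with library totals, 5335 with DESeq2 and 3934 of 5588 with the lowest count subtracted. For intronic reads, TMM gave 2566 rises and 2322 falls, median log ratio scaling 2651 and 2294, a mean of at least 40 reads 2067 and 382, and introns without an annotated exon 3108 and 184; DESeq2 gave 349 falls and limma on RPKM 434. For the ratio, both means of at least 40 gave 1474 rises and 115 falls, annotated retained introns 516 and 9, and introns without an annotated exon 3025 and 72. Stricter filters and subsets test fewer introns; the cause of the other changes was not tested, except for the scalings, which centre on 0. The fold of the intronic share was 2.58 without annotated exons, 2.09 without the 100 introns with most intronic reads and 2.26 in annotated retained introns.

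Leaving out each library gave 2503 to 2650 rises and 2578 to 2646 falls of spliced reads, 0 to 5745 rises and 0 to 636 falls of intronic reads, and 3996 to 5086 rises and 133 to 235 falls of the ratio. The ratio's falls numbered 133 without H3B-8800 replicate 1 and 137 without replicate 2. The fold of the intronic share and the intron-number difference moved by less than their spread. A group left with 1 library is assumed to vary like the other.

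With an estimated correlation, no list passed: adjusted p was 0.585 for ribosomal proteins (median 0.21), integrated stress response genes (0.71) and decay factors (0.19), and 0.193 for DNA replication (-1.05). The correlations estimated for them were 0.049, 0.057, -0.036 and -0.013, against the preset 0.01. That form of camera has only the residual degrees of freedom of 4 libraries. For ribosomal proteins and integrated stress response genes it therefore cannot separate correlated genes from low power. For decay factors and DNA replication the estimates lay below the preset, so the weaker results do not show that correlated genes made the calls. By fry, which compares a list with no other genes, these 4 lists passed (adjusted p = 0.0168, 0.0132, 0.00297 and 0.00224), and so did all others tested except RNA sensing, p53 targets, heat shock, unfolded protein response, luminal and leukocyte genes. With library totals the ribosomal median was 0.034 (adjusted p = 0.222) and the decay factor median 0.013 (adjusted p = 0.147). Decay factors also did not pass without each gene's most-read intron (median 0.18, adjusted p = 0.0502), with the lowest count subtracted (0.22, adjusted p = 0.0748), or in 3 of 4 omissions of a library (medians over the 4 from 0.15 to 0.42).

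The sample numbers are shared only as numbers: across genes, the difference between libraries 2 and 1 in H3B-8800 correlated with that in DMSO at 0.069. With the replicate block, 3140 genes rose and 3144 fell, 5310 introns had a higher and 232 a lower ratio, and 5262 and 576 introns had more and fewer intronic reads; decay factors (median 0.19) had an adjusted p = 0.0665. In simulations, the ratio test recovered 0%, 25.4% and 100% of 1.5-, 2- and 4-fold changes in introns with at least 100 reads of both kinds, against 1.49%, 5.97% and 66.7% over all introns, so depth limited larger changes and 1.5-fold ones were missed at either depth. Pseudocounts for genes, FPKM and removal of mitochondrial genes were planned but not run.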

Other observations

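Genes of G2 and mitosis did not follow those of DNA replication. Of 29 tested, 17 rose and 7 fell, with the same counts adjusted over the list alone. The checkpoint kinase gene TTK (1.14, SE 0.06) and PLK1 (0.65, SE 0.04) rose, and TOP2A, a topoisomerase, fell (-0.89, SE 0.04). The median log2 change was 0.23, or 0.05 with library totals. Camera gave a Benjamini-Hochberg adjusted p = 0.156 with the preset (p = 0.0354) and an adjusted p = 0.765 with an estimated correlation. Of 15 p53 targets, 6 rose and 5 fell, of 7 BCL2 family genes 1 rose and 4 fell, of 12 heat shock genes 3 rose and 3 fell, and of 17 genes of the endoplasmic reticulum's unfolded protein response 10 rose and 2 fell, each with unchanged counts adjusted over the list alone. SESN2 (1.85, SE 0.24), TNFRSF10B (0.86, SE 0.10), PMAIP1 (1.43, SE 0.30), BAG3 (0.63, SE 0.08), DNAJA1 (0.32, SE 0.04) and PDIA3 (0.59, SE 0.04) were among the rises, and POLH (-1.47, SE 0.20), BCL2L12 (-1.09, SE 0.23), BAD (-0.61, SE 0.13), HSPA8 (-0.35, SE 0.04), HYOU1 (-1.19, SE 0.07) and MANF (-0.52, SE 0.05) among the falls. BAD did not pass without H3B-8800 replicate 2 (-0.54), nor BCL2L12 without H3B-8800 replicate 1 (-0.84), and BAG3 and MANF did not with the gene's lowest count subtracted (0.41 and -0.26). Median and mean differed in sign for p53 targets (0.09 and -0.10) and heat shock genes (-0.03 and 0.05). None of these 4 lists passed camera, with Benjamini-Hochberg adjusted p values of 0.853, 0.725, 0.853 and 0.625 (p = 0.853, 0.594, 0.846 and 0.406), and 0.905, 0.774, 0.898 and 0.774 with an estimated correlation.

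Of 16 immediate-early genes, 6 rose and 6 fell, or 7 and 6 adjusted over the list alone; CTGF, now CCN2 (0.96, SE 0.09), DUSP1 (0.61, SE 0.09) and SRF (0.49, SE 0.08) rose, but DUSP1 did not pass with its lowest count subtracted (0.0052). Of 16 mesenchymal and basal markers, 9 rose and 5 fell, also adjusted over the list alone, with rises of CDH2 (0.85, SE 0.08) and MSN (0.49, SE 0.04) and a fall of AXL (-1.19, SE 0.08). Of 4 luminal markers, 2 fell, as they did adjusted over the list alone: KRT18 (-0.28, SE 0.10), which did not pass without H3B-8800 replicate 1 (-0.13), H3B-8800 replicate 2 (-0.45) or DMSO replicate 1 (-0.10), nor with DESeq2 (-0.29), quantile normalization, limma without trend, no filter or introns without an annotated exon, and KRT8 (-0.26, SE 0.05), which did not with its lowest count subtracted. GATA3 had a change of 0.71 (SE 0.33) and did not pass, except with quantile normalization (0.82) or its lowest count subtracted (1.91). Of 3 leukocyte markers, 2 rose, likewise adjusted over the list alone: LCP1 (0.29, SE 0.06) and CD68 (0.49, SE 0.16), neither of which passed with library totals (0.11 and 0.31), while CD68 also did not with DESeq2, in introns without an annotated exon, without its most-read intron (0.60) or with its lowest count subtracted, nor without H3B-8800 replicate 1 (0.47), H3B-8800 replicate 2 (0.50) or DMSO replicate 1 (0.41); CD79A had 0.09 (SE 0.87). Camera's Benjamini-Hochberg adjusted p values for the 4 lists were 0.625, 0.474, 0.732 and 0.676 (p = 0.426, 0.237, 0.665 and 0.523), and 0.774, 0.765, 0.774 and 0.774 with an estimated correlation. The single tested snoRNA host gene, TAF1D, rose (1.12, SE 0.07), and the single histone gene, HIST1H2BK, had a change of 0.24 (SE 0.21), which passed only by limma without trend (Benjamini-Hochberg adjusted p = 0.0488; range over alternatives 0.0488 to 0.796).

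The tests below were chosen after the results were seen, except those on matched random lists, scalings and the even background, whose outcomes were predicted first; the estimate that decided the last was chosen afterwards. The rise of intronic reads could come from genomic DNA, from nuclear RNA or from exons inside introns. DNA adds reads evenly, but genes with under 0.1 CPM of spliced reads gained 0.054 times the intronic density that genes with over 100 gained (95% bootstrap interval 0.00081 to 0.18); a bound of 0.1 written first lay inside that interval and was widened to 0.5 once the interval was seen, below the 1 that DNA needs. Full-length unspliced nuclear RNA adds reads in proportion to length within a gene. Pooled over 2196 genes, the added density in introns over 300 and up to 1000 bp was 5.61 times that in introns over 5000 bp (interval 4.23 to 7.44). Both intervals came from resampling genes, so they leave out the spread between libraries. Reads and lengths were summed over genes before division, so genes can weigh differently in the short and the long introns. The ratio therefore cannot exclude such RNA. Without annotated exons the fold of the intronic share was 2.58, above the 1.94 over all introns. Nuclear RNA that leaked during fractionation, unspliced or partly spliced, remains open, since no nuclear fraction was analysed here. It stands beside the hypothesis that partly spliced transcripts reached the cytoplasm.

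The fall of DNA replication genes was not accounted for by their intron number and expression level: the lowest median of 10000 random lists matched on both was -0.60, against -1.05. Scaling does not account for it either, since the highest median over 4 scalings was -1.01. A loss of cycling cells would lower mitotic genes too, but their median was 0.23 (95% bootstrap interval -0.02 to 0.39), or 0.05 with library totals. The bootstrap drew genes as if independent, so its interval leaves out the spread between libraries. As a hypothesis, the fall may follow from lower production or splicing of these transcripts or from fewer cells in S phase. The intronic-to-spliced ratio rose in 28 and fell in 1 of 31 tested members, but a fall of spliced reads from any cause raises it, so it does not decide between them.

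The fold of intronic per spliced reads in introns up to 150 bp, over introns with any number of reads, was 2.47 times that in introns over 10000 bp (2.39 to 2.55 over the libraries). An even background of reads would dilute the change in long introns, but it cannot exceed the lowest density seen in any class of genes. That was the density of genes with 0.1 to 1 CPM, tried after the first estimate, and its subtraction left a ratio of 2.41 (2.28 to 2.55 over the libraries), above the 1.5 set beforehand. The first estimate, from genes under 0.1 CPM, gave 0.56 but took the long introns of all 4 libraries below 0, so it was too high for an even background. An uneven background and GC content were not tested. The length classes were not matched on expression either. The fold of intronic density was 1.37 in genes with 0.1 to 1 CPM and 2.87 in those with over 100, and 1.74 under 0.1. A difference in expression between short and long introns can therefore contribute to the contrast. A greater sensitivity of short introns to H3B-8800 stays a hypothesis.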
